A study of Mus musculus with 8 samples.

How the data were processed

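Poly-A RNA of mouse atrial cardiomyocytes was extracted with a Direct-zol kit and on-column DNase digestion and turned into libraries with the Takara SMART-Seq v4 low-input kit, per the labels' protocols. The 8 samples fall into 2 groups of 4 by their titles, P0 and P28, all wild type and untreated. Per the submitters' processing notes, the reads were handled with the mm10 genome, HTSeq (read counting per gene) and DESeq2 (normalization). Tool versions, the aligner, the gene annotation and the strand setting are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart.

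The deposited values are a signal per gene, read counts that the authors divided by 1 size factor per library, as the values themselves show. In every column all values were whole multiples of 1 step (100% whole within a tolerance of 0.1 reads), so the reads behind them were recovered by dividing by that step. The smallest total of a gene over the 8 libraries was 10 reads. A second deposited table held the same P28 libraries, normalized in another set: its recovered reads equalled those of the main table for 100% of 19647 shared genes in each library, and it was not used further. In it, 3 columns of samples outside the series were not used in any step. The main table had 22138 rows. The 753 rows without a gene name or ID held 0.147% to 0.261% of the reads of a library and stayed out of library sizes and tests. Of 21385 genes with an ID, 21254 matched GENCODE M21, the mouse annotation on build mm10, by Ensembl ID, and coordinates are from there. Among the symbols, 24 had been turned into dates and 13 stood on more than 1 ID, so genes were handled by ID. Hand1, Adgre1, Lin28a, Lep, Ahsp and Sftpc, which stand in the gene lists, were not analysed here.

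The precision of a value follows from the recovered reads, 17050389 to 61215165 per library. At these depths 3 reads over a group correspond to 0.466 normalized counts at P0 and 1.13 at P28, and folds against a group without reads are lower bounds against that floor. For groups with 1 to 3 reads, the ratio is given with its 95% exact counting interval. Reads were not marked with molecular identifiers, so such intervals cover counting error only.

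The main test was limma (version 3.58.1, lmFit and eBayes with a trend, in R 4.3.3) on log2 of the normalized count plus a pseudocount of 1. It used the 16097 genes with a mean of at least 10 over the 8 libraries, was two-sided, and took group as the only term. Adjusted p-values are Benjamini-Hochberg values and calls are at 0.05. A count test was not the main test because the deposited values are normalized. Both edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 (Wald test) were run on the recovered reads as alternatives. For gene lists, camera was used with a preset correlation of 0.01 on the lists with at least 5 tested members, adjusted over the 33 lists, and again with an estimated correlation, and fry as a self-contained test. The ratio of 16 isoform pairs and the share of mitochondrial mRNAs were compared with exact two-sided permutation tests over all 70 assignments, whose smallest p is 0.0286. The lists, the pairs, the tests and the rule for naming genes were fixed before the data were examined. The rule names 21 anchor genes, the 12 largest rises and 12 largest falls among called genes with a mean of at least 100 in the higher group, groups that do not overlap and a symbol that is not a predicted or clone name, for each list the 2 members of highest mean, the 2 largest called rises and the 2 largest called falls, and both genes of each pair.

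The fit was tested on simulated libraries for the comparison of P28 with P0, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 16117 tested. There limma recovered 80.3% of the genes changed 4-fold, 52.2% of those changed 2-fold and 23.9% of those changed 1.5-fold, with 3 false calls among 107, edgeR recovered 80.3%, 53.7% and 23.9% with 4 false calls among 109, and DESeq2 recovered 92.4%, 64.2% and 38.8% with 26 false calls among 156. In the simulation camera called a planted list of 20 members, all simulated higher, and 0 of the others. Genes were drawn independently there, so the simulation does not test the preset correlation. It also changed few genes, whereas 58.5% of genes were called in the real data, so its rates need not hold there. Alternatives were pseudocounts of 0.5 and 10, no filter, a mean of at least 50, equal totals over nuclear genes, trimmed mean of M-values (TMM) factors, quantile normalization, the replicate number as a block, limma without a trend, edgeR, DESeq2 and each library left out in turn. Added after the data were seen were a rescaling to equal means of the adult sarcomere list (called cardiomyocyte scaling), thinning of all libraries to the depth of the shallowest, and the comparison without the P28 libraries 3 and 4. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.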

Results

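Poly-A RNA was profiled in atrial cardiomyocytes, the contractile cells of the upper heart chambers, isolated from the atria of untreated wild-type mice at postnatal day 0 (P0) and postnatal day 28 (P28). There were 2 groups of 4 libraries each, and the design asks how the transcriptome of these cells differs between the stages. The values are normalized read counts per gene, from which the whole reads behind each value were recovered. The P0 libraries held 44557762, 52891473, 61215165 and 46272964 reads in named genes, and the P28 libraries 36350160, 27428972, 17050389 and 18079912, so every P0 library was deeper than every P28 library. Replicates were not duplicates of one another, since within-group pairs differed by 11.95 to 158.59 times the variance of read sampling (chi-square per degree of freedom). No label says that the libraries came from separate animals, so p-values measure only the spread between these samples. Counting intervals and floors cover counting error only.

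P28 atrial cardiomyocyte libraries held far less RNA for slow skeletal troponin I, fetal growth genes and cell cycle genes than P0 libraries, and more RNA for myoglobin, mitochondrial proteins, atrial natriuretic peptide and sarcolipin. Tnni1, the troponin I isoform of the fetal heart, stood at 71870 ± 6976 normalized counts at P0 and 428 ± 50.6 at P28 (mean ± SD, n = 4 each, as for all values that follow). Mb, which encodes the oxygen-binding protein myoglobin, went the other way, from 8174 ± 2145 to 202473 ± 17376. Markers of fibroblasts, macrophages and the epicardium were also higher at P28, and erythroid markers were higher at P0. These changes were part of a broad difference: of 16097 genes tested with limma, 4793 were higher and 4619 lower at P28 at an adjusted p below 0.05, and 2727 and 1845 of these changed at least 2-fold. The first principal component separated the stages and held 76.6% of the variance. Correlations between libraries were 0.958 to 0.986 within a stage and 0.832 to 0.860 between stages. The balance of directions depended on the scaling. With equal totals over nuclear genes, 3898 genes were higher and 6053 lower, so that 39.2% of calls were higher against 50.9% with the deposited scaling, and the median log2 fold change of all genes moved from −0.01 to −0.20.

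**Figure D1:**
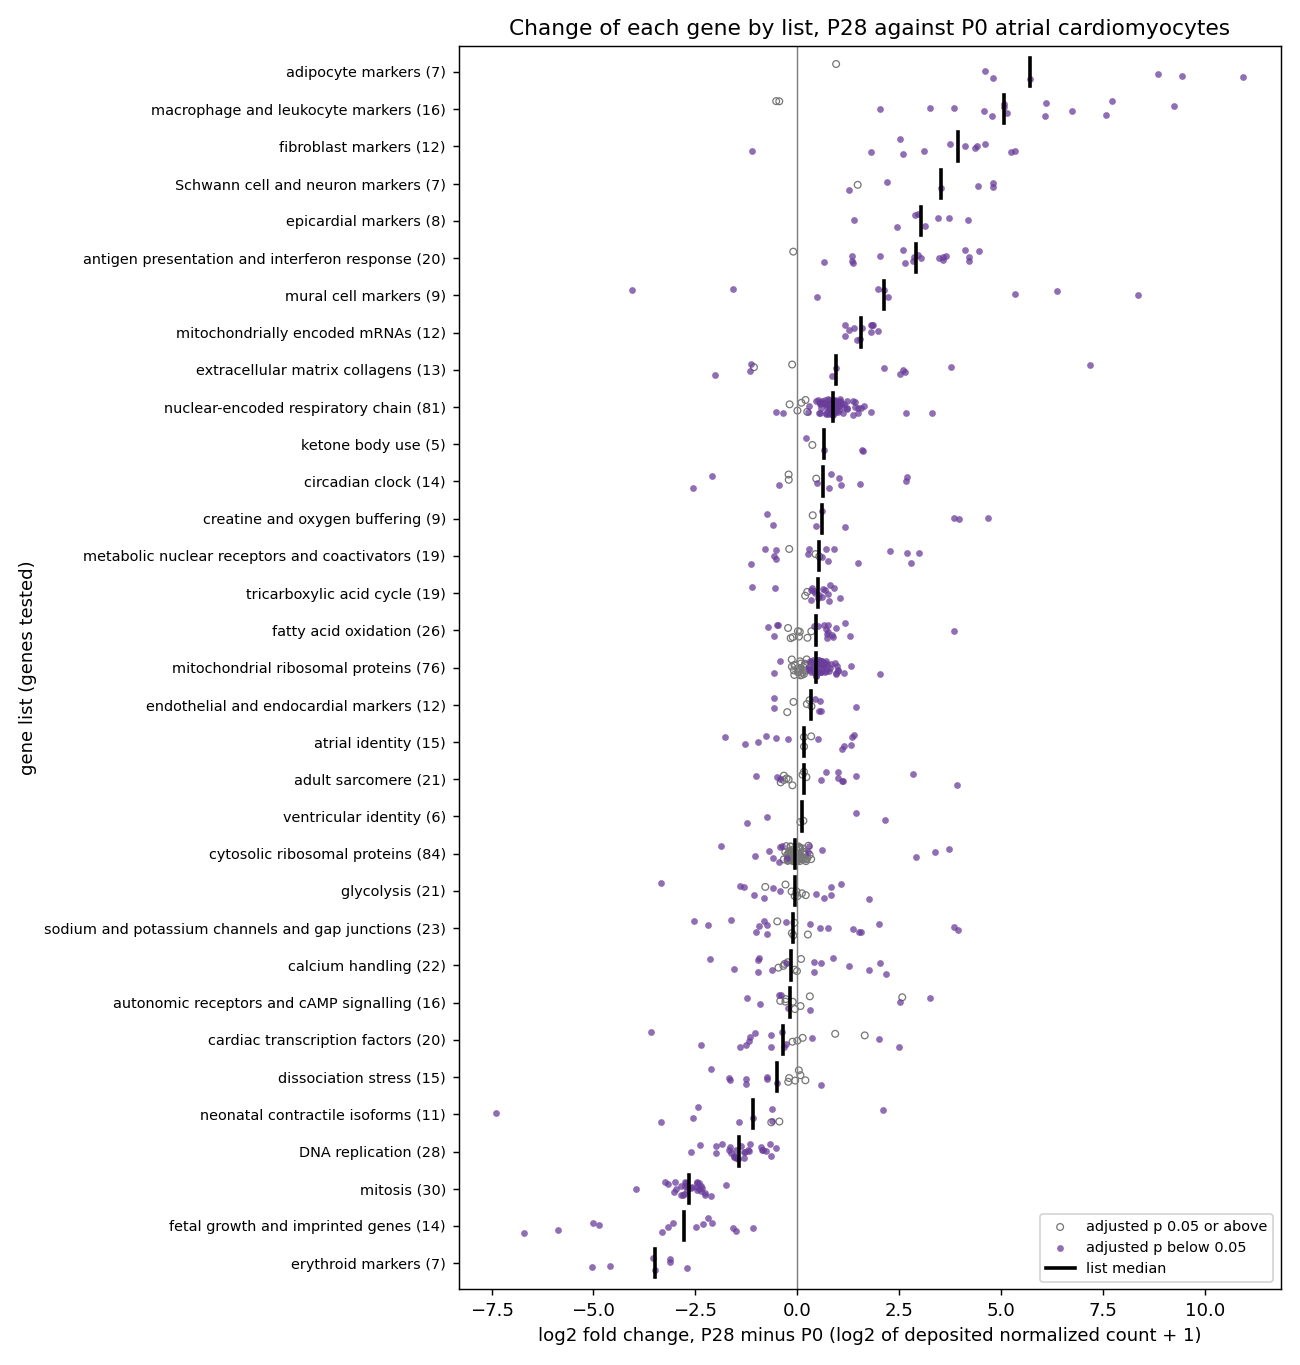
Log2 fold change of every tested gene in each of the 33 lists with at least 5 tested members (horizontal axis, P28 minus P0, on log2 of the normalized count plus 1), with lists ordered by their median (black bars) and the number of genes tested in parentheses. Filled points have a limma adjusted p below 0.05 and open points do not; list medians run from −3.49 for erythroid markers to 5.70 for adipocyte markers.

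Contractile protein genes of the neonatal type were mostly lower at P28. In the list of fetal, slow skeletal and smooth muscle isoforms, 8 of 11 tested members fell and 1 rose (median log2 fold change −1.10; camera adjusted p = 0.00159, but adjusted p = 0.214 with an estimated correlation). Tnni1 fell by 7.39 on the log2 scale (SE 0.10, adjusted p = 7.5e-12), and Acta1, skeletal alpha-actin, from 2607 ± 642 to 274 ± 139. Myl9, a smooth muscle myosin light chain, fell from 70499 ± 8014 to 26870 ± 8563. The exception was Tnni2, fast skeletal troponin I, at 272 ± 67.4 and 1151 ± 83.4. Among sarcomere genes of the mature heart, 9 of 21 rose, 3 fell and 9 did not pass the test, and camera did not call the list (median 0.16; adjusted p = 0.19), while fry did (adjusted p = 0.0059). The Z-disc protein telethonin, encoded by Tcap, rose from 11430 ± 2397 to 171001 ± 12725, a log2 fold change of 3.92 (SE 0.14, adjusted p = 5.2e-09). Tnni3, cardiac troponin I, rose from 134626 ± 32174 to 286797 ± 33958, and Myom3, an M-band protein, from 33.4 ± 11 to 249 ± 86.2. Mybpc3, cardiac myosin-binding protein C, fell from 86006 ± 9746 to 43034 ± 8171. Several of the most abundant contractile mRNAs did not pass the test. Myh6, alpha myosin heavy chain, stood at 815361 ± 146291 and 694125 ± 12931, Tnnt2 at 328818 ± 44900 and 381963 ± 35445, and Actc1 at 356896 ± 23043 and 278099 ± 85876. Actc1 was called lower without P28 replicate 2 (log2 fold change −0.58, adjusted p = 0.026). With equal nuclear totals both Actc1 (−0.60, adjusted p = 0.014) and Myh6 (−0.40, adjusted p = 0.040) were called lower, as they were with quantile normalization (−0.98 and −0.77) and the cardiomyocyte scaling (−0.92 and −0.72). Tnnt2 was called lower under the cardiomyocyte scaling alone (−0.28, adjusted p = 0.020). Actc1, Myh6 and Tnnt2 belong to the list that sets this scaling, so their calls under it are no independent evidence of a fall. The scaling lowered every gene by the list mean (0.50), which lay above the list median through members such as Tcap and Myom3 (2.84). Myh7, beta myosin heavy chain, stood at 12122 ± 6662 and 11607 ± 7114, with P28 replicate 3 at 1170 and the other P28 libraries between 13173 and 16779.

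**Figure D2:**
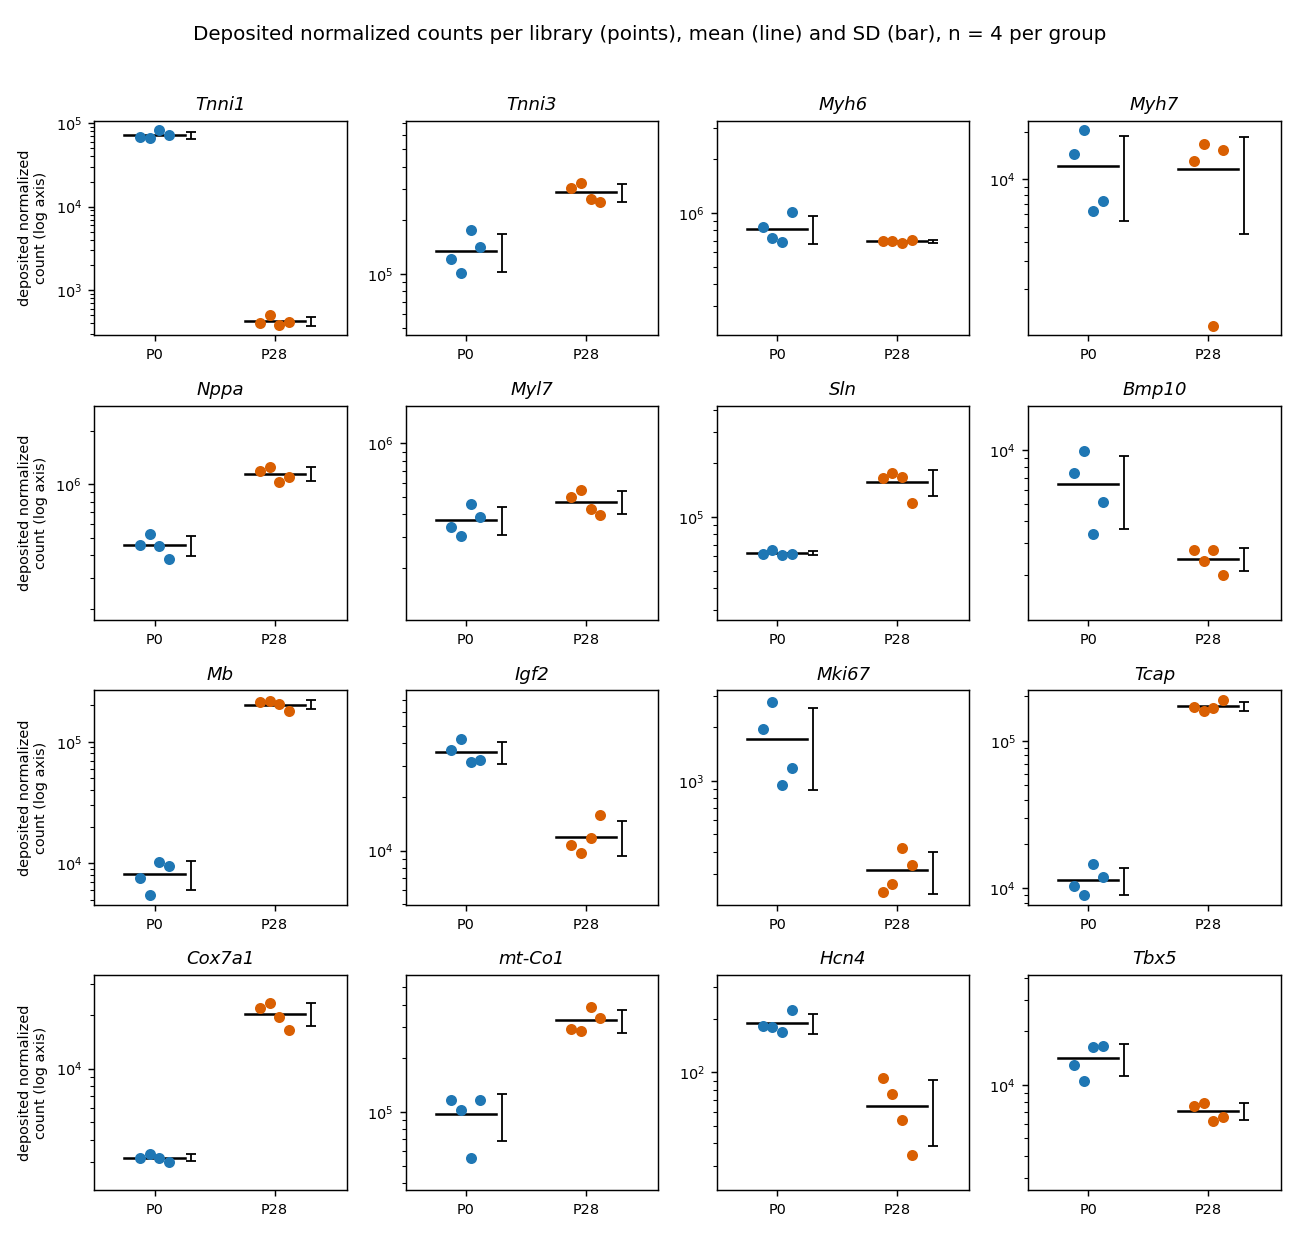
Normalized counts of 16 genes in each library (points; vertical log axis) at P0 and P28, with the group mean (line) and SD (bar), n = 4 per group. Tnni1 falls from a mean of 71870 to 428 and Mb rises from 8174 to 202473, while the Myh6 means of 815361 and 694125 lie close together.

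Genes of atrial identity did not move in 1 direction: 6 of 15 rose, 6 fell and 3 did not pass the test (median 0.16; camera adjusted p = 0.684, fry adjusted p = 0.0448). Those that rose included Nppa, atrial natriuretic peptide, from 455444 ± 59732 to 1144980 ± 99028 (log2 fold change 1.34, SE 0.18, adjusted p = 7.1e-05). Sln, the calcium pump regulator sarcolipin, rose from 62758 ± 1965 to 157312 ± 25595. Stard10 rose from 15335 ± 5274 to 38570 ± 5018 and Kcnj3, a subunit of the acetylcholine-gated potassium channel, from 3297 ± 566 to 6909 ± 218. Kcna5, the ultrarapid potassium channel, was at 449 ± 233 and 936 ± 320 (adjusted p = 0.0164), a call lost without P28 replicate 2 (log2 fold change 0.95, adjusted p = 0.052) and under the cardiomyocyte scaling (0.64, adjusted p = 0.150). Members that fell included Tbx5, an atrial transcription factor, from 14074 ± 2838 to 7114 ± 798 (log2 fold change −0.97, SE 0.14, adjusted p = 0.000159), the growth factor gene Bmp10, from 6482 ± 2855 to 2465 ± 362, and the calcium channel gene Cacna1d, from 568 ± 152 to 163 ± 31.3. Myl7, the atrial light chain, at 371920 ± 66504 and 468147 ± 69005, and Nr2f2, at 1735 ± 133 and 1940 ± 116, did not pass the test, though DESeq2 on the recovered reads called Myl7 higher (log2 fold change 0.33, adjusted p = 0.042), and under the cardiomyocyte scaling Nr2f2 was called lower (−0.34, adjusted p = 0.038). Of 6 tested ventricular genes, 2 rose, 2 fell and 2 did not pass (median 0.11; adjusted p = 0.953). Myl3, a ventricular light chain, rose from 8071 ± 1919 to 21949 ± 6425 and Hey2, a transcription factor, from 10 ± 6.3 to 45.5 ± 30. Irx5 fell from 490 ± 49.4 to 215 ± 69.8, and Myl2, the main ventricular light chain, stayed near 199 ± 115 and 197 ± 85.4 without passing the test. The medians of the atrial, ventricular and adult sarcomere lists were negative under equal nuclear totals (−0.02, −0.07 and −0.02) and quantile normalization (−0.27, −0.19 and −0.19), and camera called none of these 3 lists there. Under the cardiomyocyte scaling the atrial and ventricular medians were −0.34 and −0.39, without a call.

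Developmental transcription factors of the heart fell in 12 of 20 cases and rose in 3 (4 adjusted over the list alone), with a median of −0.35 and a camera adjusted p of 0.0252 (adjusted p = 0.479 with an estimated correlation). This list call was lost without the P28 libraries 3 and 4 (adjusted p = 0.056) and with quantile normalization (adjusted p = 0.059). Tbx20 fell from 9544 ± 3273 to 1798 ± 191 and Gata4 from 10010 ± 1099 to 4350 ± 113. Those that rose were Prdm16, from 45 ± 13.4 to 254 ± 38.9, Tbx3, a regulator of the conduction system, from 121 ± 40.3 to 470 ± 92, and Hopx, from 8702 ± 445 to 11193 ± 872. The Hopx call was lost with equal nuclear totals (adjusted p = 0.052), and its direction turned under the cardiomyocyte scaling (log2 fold change −0.14, adjusted p = 0.175).

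Cell cycle genes fell throughout. All 30 mitosis genes were lower at P28 (median −2.66; camera adjusted p = 2.2e-13, and adjusted p = 0.334 with an estimated correlation), as were all 28 DNA replication genes (median −1.42; camera adjusted p = 1.3e-10, and adjusted p = 0.214 with an estimated correlation). Mki67, a marker of cycling cells, stood at 1718 ± 832 and 315 ± 82.9 (log2 fold change −2.35, SE 0.31, adjusted p = 6.3e-05). Bub1, a spindle checkpoint kinase, fell from 693 ± 368 to 43.5 ± 19.5 and Ccnb1, cyclin B1, from 2052 ± 1086 to 198 ± 35.1. Rrm2, a subunit of ribonucleotide reductase, fell from 3222 ± 454 to 630 ± 157 and the replicative helicase gene Mcm6 from 3416 ± 227 to 1392 ± 193. P0 libraries 1 and 2 held more Mki67 (1959 and 2783) than P0 libraries 3 and 4 (943 and 1186), and all 4 exceeded every P28 library. Erythroid markers moved the same way. All 7 tested members were lower at P28 (median −3.49), with Hba-a1 at 242282 ± 27266 and 34454 ± 28296. The Hba-a1 values in P28 replicates 1 to 4 were 28287.8, 19130.6, 14390.3 and 76006.5.

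All 14 tested fetal growth and imprinted genes were lower at P28 (median −2.78; camera adjusted p = 1.5e-08, and adjusted p = 0.214 with an estimated correlation). The maternally expressed non-coding RNA H19 fell from 45207 ± 7220 to 4957 ± 657 and Igf2, insulin-like growth factor 2, from 35561 ± 4964 to 11983 ± 2680 (log2 fold change −1.58, SE 0.15, adjusted p = 6.0e-06). Dlk1, an imprinted membrane protein, fell from 2352 ± 1813 (2765, 4746, 1038 and 860 in the P0 libraries) to 17.5 ± 6.01, and Igf2bp3, a fetal RNA-binding protein, from 1102 ± 77.2 to 18.9 ± 7.04. The mean of this list was higher in P0 replicates 1 and 2 (11.53 and 11.89, log2) than in 3 and 4 (10.97 and 11.01), as were those of endothelial markers (12.74 and 13.03 against 12.38 in both) and, over a narrow range, erythroid markers (13.47 and 13.51 against 13.40 and 13.38).

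Genes of mitochondrial energy production were mostly higher at P28. In the nuclear-encoded respiratory chain, 74 of 81 tested subunits rose and 2 fell (75 and 2 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 9.7e-16, and adjusted p = 0.396 with an estimated correlation). Cox7a1, the heart and muscle isoform of a cytochrome oxidase subunit, rose from 3171 ± 135 to 20246 ± 2987 and Cox6a2, another such isoform, from 27936 ± 1574 to 78150 ± 10932. Cox4i2 rose from 29.6 ± 10.2 to 295 ± 50.8, counts far below those of Cox7a1 and Cox6a2. Pericyte genes rose in the same libraries, and which cells held the Cox4i2 RNA was not tested. Atp5b, an abundant ATP synthase subunit, was at 199134 ± 11499 and 228887 ± 21270 and did not pass the test, but was called lower with quantile normalization (log2 fold change −0.68, adjusted p = 5.6e-05) and the cardiomyocyte scaling (−0.31, adjusted p = 0.012). All 12 tested mRNAs of the mitochondrial genome rose (median 1.56; camera adjusted p = 3.9e-06, and adjusted p = 0.267 with an estimated correlation). Among them mt-Co1 went from 97416 ± 29103 to 325673 ± 47641 and mt-Nd2 from 13120 ± 1543 to 47667 ± 4554. Together the mitochondrial mRNAs made up 0.980% ± 0.145 of the normalized counts of a P0 library and 2.58% ± 0.44 of a P28 library, higher in 4 of 4 P28 libraries (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). Counts of mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l were uncertain, since most of these genes share sequence with nuclear copies. Parts of mt-Co1 and mt-Nd4 also occur in nuclear copies (51.1% and 62.2% of their 50-base words). Mitochondrial ribosomal proteins rose in 51 of 76 cases and fell in 2 (median 0.46; camera adjusted p = 7.8e-07, and adjusted p = 0.531 with an estimated correlation), with Mrps6 at 2087 ± 245 and 8473 ± 1273. Tricarboxylic acid cycle enzymes rose in 15 of 19 cases (16 adjusted over the list alone) and fell in 2 (median 0.50; camera adjusted p = 0.00333, and adjusted p = 0.542 with an estimated correlation). Sdhb rose from 16772 ± 1280 to 35133 ± 5841, whereas Idh2 fell from 71283 ± 4340 to 33114 ± 2928. The cycle list lost its call with edgeR (adjusted p = 0.060) and DESeq2 (adjusted p = 0.064) on the recovered reads. Under the cardiomyocyte scaling neither the cycle list (median −0.002, adjusted p = 0.156) nor the mitochondrial ribosomal list (median −0.05, adjusted p = 0.065) was called.

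Fatty acid genes were less uniform. Of 26 tested genes of fatty acid uptake and oxidation, 14 rose, 4 fell and 8 did not pass the test (median 0.46; camera adjusted p = 0.0394, and adjusted p = 0.757 with an estimated correlation). Fabp3, a fatty acid-binding protein, rose from 22340 ± 5457 to 49082 ± 4986, Lpl, lipoprotein lipase, from 18396 ± 614 to 45328 ± 6834, and Ucp3 from 54.1 ± 33.9 to 645 ± 242. Cpt1b, which imports long-chain fatty acids into muscle mitochondria, fell from 3201 ± 463 to 1972 ± 468 (log2 fold change −0.72, SE 0.17, adjusted p = 0.00366), and Acadl, a dehydrogenase of the pathway, from 41364 ± 8941 to 27678 ± 4365. The list call was lost without P0 replicate 1 (adjusted p = 0.056), P0 replicate 2 (0.127) or P28 replicate 4 (0.095), and with edgeR (0.121), DESeq2 (0.141), quantile normalization (0.063), limma without a trend (0.057) and cardiomyocyte scaling (median −0.04, adjusted p = 0.156). Adipocyte markers varied with this list among the P28 libraries: both list means were lowest in replicate 3 (5.25 for adipocyte and 13.12 for fatty acid genes, log2) and highest in replicate 4 (11.09 and 13.59), and Lpl is also a transcript of adipocytes. The Acadl call was lost without the P28 libraries 3 and 4 (log2 fold change −0.47, adjusted p = 0.067). Ketone body use rose in 4 of 5 genes (median 0.65; camera adjusted p = 0.0456, and adjusted p = 0.229 with an estimated correlation), with Oxct1, the enzyme that activates ketone bodies, at 5343 ± 1560 and 15885 ± 1910. Without P0 replicate 2, P28 replicate 2 or P28 replicate 4, this list was not called (adjusted p = 0.070, 0.055 and 0.066), and 11 settings besides the estimated correlation ended its call, among them edgeR (0.153) and DESeq2 (0.177). Like the adipocyte markers, the ketone list had its lowest P28 mean in replicate 3 (11.60, log2) and its highest in replicate 4 (11.90). Creatine and oxygen buffering genes rose in 6 of 9 cases (7 adjusted over the list alone) and fell in 2 (median 0.60; camera adjusted p = 0.0252, and adjusted p = 0.42 with an estimated correlation). Mb rose by a log2 fold change of 4.67 (SE 0.18, adjusted p = 7.3e-09) and Ckmt1, a mitochondrial creatine kinase, from 36.6 ± 10.2 to 576 ± 131, while the cytosolic muscle kinase gene Ckm fell from 93792 ± 10221 to 56498 ± 12251. Glycolysis genes went both ways, with 6 of 21 higher and 7 lower (median −0.07; adjusted p = 0.591), among them Slc2a4, the insulin-responsive glucose transporter, at 3366 ± 220 and 11434 ± 2055 and Aldoc at 760 ± 131 and 75.2 ± 22.4. Metabolic nuclear receptors and coactivators rose in 11 of 19 cases (12 adjusted over the list alone) and fell in 5, a list that camera did not call (median 0.54; adjusted p = 0.161) and fry did (adjusted p = 0.00451). Perm1 rose from 744 ± 111 to 5145 ± 1147, Rxrg from 227 ± 92.4 to 1688 ± 247 and Esrra from 1897 ± 232 to 3231 ± 635. Ppargc1a fell from 4302 ± 473 to 1957 ± 109 and Esrrg from 774 ± 134 to 444 ± 69.9. The Esrra call was lost under the cardiomyocyte scaling (log2 fold change 0.25, adjusted p = 0.077). The mean of this receptor list at P28 was also lowest in replicate 3 (9.95, log2) and highest in replicate 4 (10.20).

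Within libraries, isoform ratios changed in 11 of 16 pairs fixed in advance, by an exact two-sided permutation test with Benjamini-Hochberg adjustment. Each of the 11 had an exact p of 0.0286, the smallest the design allows, and an adjusted p of 0.0416, with the groups fully apart. The counts cover all 16 pairs, and 1 of the 11 is not described here. Ratios within a library do not depend on the scaling, and they compare libraries, not absolute amounts of the isoforms. They can change with the mix of cells in a library, and markers of other cell types differed between the stages. Whether the ratios changed within cardiomyocytes was therefore not tested. Tnni1 made up 35.3% ± 3.41 of Tnni1 and Tnni3 at P0 and 0.149% ± 0.013 at P28. Hcn4, a pacemaker channel, made up 88.6% ± 4.93 of Hcn4 and Hcn2 at P0 and 15.1% ± 4.23 at P28. The share of Slc2a1 in the glucose transporter pair with Slc2a4 went from 42.2% ± 15.2 to 7.48% ± 1.01, that of Hk1 against Hk2 from 91.3% ± 2.77 to 71.3% ± 1.76, and that of Acta1 against Actc1 from 0.733% ± 0.216 to 0.0949% ± 0.0229. In 3 cytochrome oxidase pairs the share of the isoform expressed in most tissues fell: Cox7a2 from 79.4% ± 0.75 to 51.8% ± 0.55, Cox8a from 74.3% ± 1.11 to 39.2% ± 3.02 and Cox6a1 from 28.2% ± 0.65 to 10.1% ± 1.87. Ckb rose against Ckm, from 8.62% ± 0.36 to 17.1% ± 1.49. Eno1 against Eno3 went from 43.5% ± 10.4 to 20.2% ± 6.25, a call lost without P0 replicate 1 or 2 (adjusted p = 0.083 in both). Pairs that did not pass were Myh7 and Myh6 (1.52% ± 0.93 and 1.63% ± 0.99), Myl2 and Myl7 (0.0507% ± 0.0242 and 0.0407% ± 0.0123), Cpt1a and Cpt1b (52.7% ± 3.92 and 52.3% ± 7.18), Ldha and Ldhb (52.4% ± 9.12 and 50.6% ± 0.34) and Pgam1 and Pgam2 (6.42% ± 2.60 and 3.47% ± 1.09).

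Calcium handling and electrical genes changed in both directions. Of 22 calcium handling genes, 8 rose and 7 fell (8 adjusted over the list alone); the median was −0.15, the mean 0.03 and the camera adjusted p 0.96, with a test direction up. Ryr2, the calcium release channel, rose from 6994 ± 1155 to 12686 ± 603, S100a1 from 4360 ± 265 to 19716 ± 2647 and Hrc from 1442 ± 235 to 5848 ± 314. Slc8a1, the sodium-calcium exchanger, fell from 2492 ± 611 to 562 ± 125 and Casq1 from 3309 ± 220 to 1179 ± 391. Atp2a2, the main calcium pump, at 296345 ± 44844 and 314118 ± 35177, did not pass the test, but was called lower with quantile normalization (log2 fold change −0.41, adjusted p = 0.013) and the cardiomyocyte scaling (−0.41, adjusted p = 0.002). Sodium and potassium channels and connexins rose in 9 of 23 cases and fell in 9 (median −0.10, mean 0.19, test direction down, adjusted p = 0.755). Hcn2 rose from 25.4 ± 13.9 to 356 ± 63.4 and Scn4b from 5.43 ± 5.36 to 72.1 ± 35.8, while Gja5, the atrial connexin 40 gene, fell from 23263 ± 7172 to 4876 ± 463 and Kcne1 from 234 ± 20 to 40.6 ± 10.2. Autonomic receptor and cyclic AMP genes rose in 3 of 16 cases and fell in 5 (4 adjusted over the list alone), with a median of −0.17, a mean of 0.29 and an adjusted p of 0.534. Adcy5, an adenylyl cyclase, fell from 4653 ± 342 to 2008 ± 367. Like the adipocyte markers, the autonomic list had its lowest P28 mean in replicate 3 (10.40, log2) and its highest in replicate 4 (11.04).

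Markers of other cell types moved with stage in libraries labelled as atrial cardiomyocytes. Fibroblast markers rose in 11 of 12 cases (median 3.93; camera adjusted p = 3.5e-07), and this was the 1 list whose call held with an estimated correlation (adjusted p = 0.0453). Dcn, decorin, rose from 4382 ± 512 to 92399 ± 5915 (log2 fold change 4.40, SE 0.10, adjusted p = 2.7e-10) and Pi16 from 422 ± 223 to 15307 ± 1252, while Postn, periostin, fell from 15395 ± 1970 to 7165 ± 1041. Macrophage and leukocyte markers rose in 14 of 16 cases (median 5.07; camera adjusted p = 2.8e-08, and adjusted p = 0.214 with an estimated correlation), with Lyz2, lysozyme, at 95.2 ± 32.1 and 19450 ± 3783. All 8 epicardial markers rose (median 3.04; camera adjusted p = 1.4e-06, and adjusted p = 0.214 with an estimated correlation), with Msln at 1706 ± 263 and 12597 ± 1991. Mural cell markers rose in 7 of 9 cases and fell in 2 (median 2.11; camera adjusted p = 0.0195, and adjusted p = 0.214 with an estimated correlation). The pericyte genes Rgs5, at 91.4 ± 18.9 and 7508 ± 378, and Vtn, at 3.87 ± 2.89 and 1253 ± 66.4, rose, and the smooth muscle gene Cnn1 fell from 4580 ± 573 to 302 ± 155. Adipocyte markers rose in 6 of 7 cases (median 5.70, also with Cfd at its bound; camera adjusted p = 0.00606, and adjusted p = 0.456 with an estimated correlation) and Schwann cell and neuron markers in 6 of 7 (median 3.52; camera adjusted p = 0.00458, and adjusted p = 0.214 with an estimated correlation). Erythroid markers fell in 7 of 7 (camera adjusted p = 6.6e-04, and adjusted p = 0.385 with an estimated correlation). Endothelial and endocardial markers were not called as a list by camera (5 of 12 higher, 2 lower, median 0.32, adjusted p = 0.526), and their median was negative, also without a call, under the cardiomyocyte scaling. Vwf rose from 5392 ± 2375 to 13700 ± 2677 and Tie1 fell from 13001 ± 3032 to 8518 ± 136. The 1 tested lung epithelium marker, Ager, fell by 2.11 on the log2 scale, and no list test was possible. Globin and class I histocompatibility genes have near-identical relatives, so their single-gene values are uncertain.

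**Figure D3:**
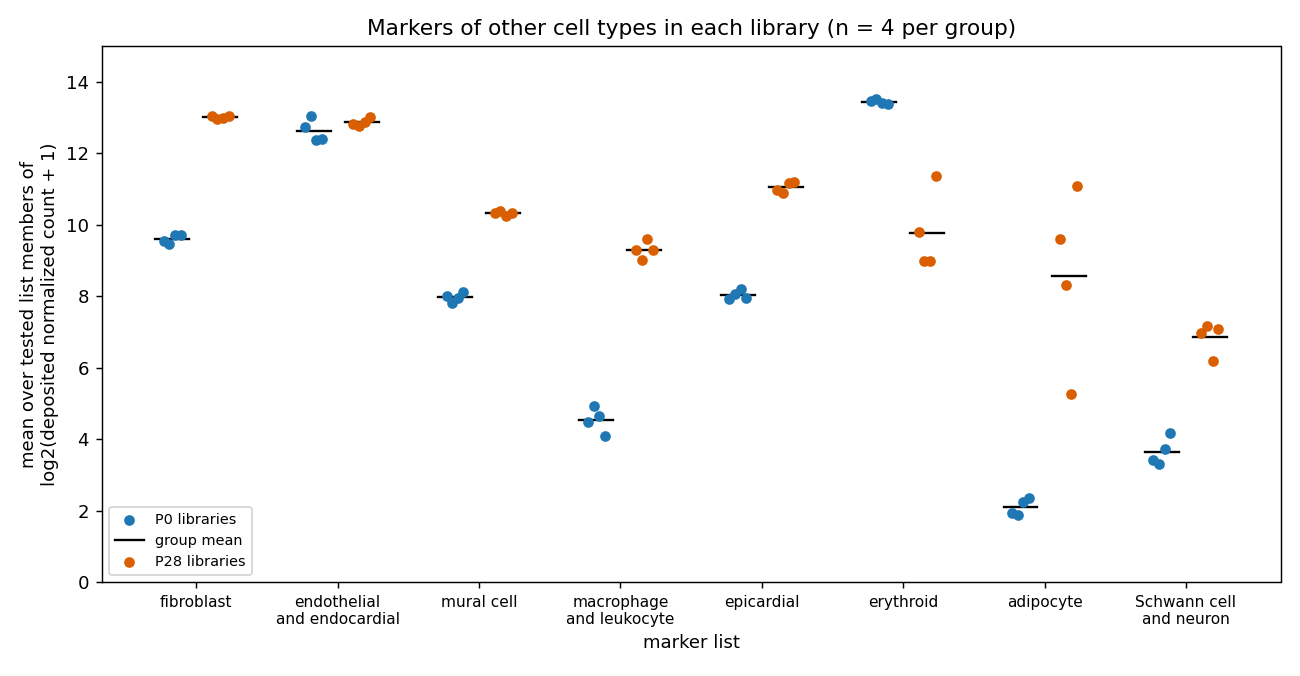
Mean of log2 of the normalized count plus 1 over the tested members of 8 marker lists of other cell types (vertical axis) in each library, with P0 libraries in blue, P28 libraries in orange and group means as lines, n = 4 per group. The P28 libraries lie above all P0 libraries for fibroblast, mural, macrophage, epicardial, adipocyte and nerve markers and below them for erythroid markers, and adipocyte means at P28 spread from 5.25 to 11.1.

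Antigen presentation and interferon genes rose in 19 of 20 cases (median 2.91; camera adjusted p = 4.1e-07, and adjusted p = 0.214 with an estimated correlation). H2-D1, a class I molecule, rose from 4384 ± 692 to 34118 ± 6990 and Ifit3, an interferon-induced gene, from 110 ± 51.8 to 2385 ± 1052, in the same libraries in which macrophage markers rose. Collagen genes rose in 8 of 13 cases and fell in 3 (4 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 0.0394, and adjusted p = 0.42 with an estimated correlation). The fibrillar Col3a1, also counted as a fibroblast marker, rose from 26873 ± 2606 to 161660 ± 5489 and Col8a1 from 17.2 ± 6.86 to 2496 ± 133. Col18a1 fell from 16556 ± 2966 to 4086 ± 574 and the basement membrane gene Col4a1 from 60896 ± 20094 to 26044 ± 273. The collagen list was not called without P0 replicate 3 (adjusted p = 0.079), P0 replicate 4 (0.052) or P28 replicate 4 (0.050), nor without the P28 libraries 3 and 4 (0.053) or with limma without a trend (0.057). Immediate early and heat shock genes, which tissue digestion can raise, fell in 8 of 15 cases and rose in 1 (median −0.51; camera adjusted p = 0.0107, and adjusted p = 0.51 with an estimated correlation). Fos fell from 47990 ± 7208 to 20200 ± 3307 and Egr1 from 45517 ± 10165 to 14026 ± 1323, while Dusp1 rose from 14561 ± 852 to 21686 ± 2693. The Dusp1 call was lost under the cardiomyocyte scaling (log2 fold change 0.06, adjusted p = 0.663).

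Clock genes and cytosolic ribosomal protein genes were not called as lists by camera, although fry, which does not compare a list with other genes, called the clock list (adjusted p = 0.00134). Of 14 clock genes, 8 rose and 3 fell (median 0.63; camera adjusted p = 0.161): Dbp rose from 937 ± 453 to 5442 ± 343 and Ciart from 82.4 ± 10.3 to 540 ± 139, while Arntl fell from 540 ± 126 to 91.2 ± 26.5 and Npas2 from 301 ± 20 to 70.8 ± 12.4. Clock transcripts vary with the time of day, and the hour of collection was not among the sample data used here. A difference in that hour between the groups cannot be told apart from stage for these genes. Of 84 cytosolic ribosomal genes, 6 rose and 8 fell (4 and 4 adjusted over the list alone), with a median of −0.05, a mean of 0.04 and an adjusted p of 0.591. Rpl3l, a paralog of striated muscle, rose from 98.1 ± 26.1 to 1009 ± 203 and Rps4l, which the annotation lists as a transcribed processed pseudogene, fell from 4442 ± 347 to 1237 ± 319. Under the cardiomyocyte scaling the ribosomal list was called lower (median −0.55, adjusted p = 0.026).

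The largest falls in the data included Tnni1, the growth factor-binding protein gene Igfbp2 (2015 ± 137 and 12 ± 4.15), the matrix gene Fbn2 (2288 ± 457 and 46 ± 25.6) and Bex1 (2143 ± 590 and 42.8 ± 18.5). Ppp1r17 and Kcnq5 had 2 reads each over the P28 libraries, so that their P0 levels were 276 times (95% counting interval 76.2 to 2280) and 154 times (42.4 to 1272) the P28 level. Both reads came from 1 library in each case. Without it, Ppp1r17 (P28 replicate 3) was at least 150-fold and Kcnq5 (P28 replicate 1) at least 66.3-fold lower at P28. Without P28 replicate 1 the Ppp1r17 ratio was 175 (48.4 to 1447). Among the largest rises, Cfd (a member of the adipocyte list), Inmt, Mmp3 and Clec10a had no read in any P0 library. Against a floor of 3 reads over the P0 group, they were at least 6650-fold, 1826-fold, 1171-fold and 1147-fold higher at P28, with 3097 ± 2775, 850 ± 327, 545 ± 216 and 534 ± 77 normalized counts. The Cfd values at P28 were 2914, 2238, 318 and 6918, and without P28 replicate 4 it was at least 3915-fold higher. Retnla had 2 P0 reads, a ratio of 3318 (918 to 27414), and Ucp1 had 3, a ratio of 8352 (2857 to 40505). The P28 values of Ucp1, the uncoupling protein of brown fat, were 3019, 260, 58.5 and 14498, and without P28 replicate 4 the ratio was 3124 (1068 to 15159). Its P0 reads all came from P0 replicate 4, without which it was at least 7410-fold higher at P28. Tuba8, an alpha-tubulin, rose from 8.18 ± 4.08 to 3918 ± 1821, Ms4a4d from 1.89 ± 2.32 to 1016 ± 61.6 and Mgl2, a macrophage lectin with a close relative in Clec10a, from 0.994 ± 1.19 to 704 ± 53.5. Pck1 varied from 89.8 to 14446 among the P28 libraries, which stood in the same order as for Ucp1. Which cells held the RNA of the genes with the largest rises was not tested.

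In the mouse annotation of build mm10 (GENCODE M21), Tnni1 (ENSMUSG00000026418) spans positions 135779434 to 135810989 of chromosome 1 and Tnni3 (ENSMUSG00000035458) positions 4518305 to 4524229 of chromosome 7. Mb (ENSMUSG00000018893) lies at 77015487 to 77050670 on chromosome 15, Tcap (ENSMUSG00000007877) at 98383811 to 98384953 on chromosome 11 and Nppa (ENSMUSG00000041616) at 148000722 to 148002079 on chromosome 4. Tbx5 (ENSMUSG00000018263) lies at 119832668 to 119885219 on chromosome 5 and Dcn (ENSMUSG00000019929) at 97479609 to 97518143 on chromosome 10. Igf2 (ENSMUSG00000048583, 142650766 to 142666816) and H19 (ENSMUSG00000000031, 142575529 to 142578143) are neighbours on chromosome 7. All of these genes are annotated as protein-coding, except H19, a long intergenic non-coding RNA, and counts were made over whole genes.

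The counts of genes in each direction came from limma on log2 of the normalized count plus 1, with a two-sided test and Benjamini-Hochberg adjustment, so fold changes of low genes are understated. Of the 33 lists tested, 22 were called, 15 higher and 7 lower, and 1 of these calls held with an estimated correlation between genes. Counts of members are over all genes tested, and those adjusted over the list alone were equal except where given. Where the cardiomyocyte scaling is named, libraries were rescaled to equal means of the adult sarcomere list, a setting added after the data were seen, under which 2604 genes were higher and 8218 lower. It lowers every log2 fold change by the mean of that list (0.50, against a median of 0.16), so a call of lower under it alone does not show a fall.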

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

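The comparisons of marker lists by their medians (leukocyte against endothelial, mitosis against adult sarcomere), the gene length test and the word search for mt-Atp8 were chosen only after the results were seen. Thinning to equal depth was added once the depths had been seen, but before its results were.

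Among 410 sets of 4 libraries, 14 held a library far from the other 3 by Dixon's 95% criterion, which chance alone passes in a share of about 0.05 of such sets. P28 replicates 3 and 4 gave 5 of these each. P28 replicate 4 stood apart for Ckmt1 (771 normalized counts; the others 485 to 527), Ucp3 (1008; 521 to 525), Eno1 (28873; 16195 to 18359), the share of Cox6a1 against Cox6a2 (12.8%; 8.84% to 9.46%) and that of Hcn4 against Hcn2 (8.81%; 16.6% to 17.9%). P28 replicate 3 stood apart for Cd163 (949; 1155 to 1168), Ppp1r17 (4.18; 0 in the others), the mean log2 value of glycolysis genes (13.11; 13.39 to 13.40), that of mitochondrially encoded mRNAs (13.08; 12.57 to 12.64) and that of the lung epithelium marker (1.63; 4.04 to 4.40). The remaining values were Kcnq5 in P28 replicate 1 (2.06; 0 in the others), Perm1 in P0 replicate 2 (578; 786 to 823), Rps4l in P0 replicate 3 (4957; 4204 to 4311) and Ucp1 in P0 replicate 4 (2.06; 0 in the others). For Ppp1r17, Kcnq5 and Ucp1 the other values were 0, so any read in the remaining library passes the criterion. The lung epithelium marker, Ager, was at only 2.09 normalized counts in P28 replicate 3. Rows with no gene name, outside every comparison, held up to 0.261% of the reads of a library.

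The number of genes past the threshold was largest in the real split. Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many genes (9412, with 0 in the highest other split). The same held for genes changed at least 2-fold (4572, with 0 in the highest other). Every other split mixes the stages, so the difference between them adds to the spread within its groups and lowers its calls. These 0 counts therefore cannot exclude chance. For the number of lists called by camera with its preset correlation, 2 of the 35 splits reached the real count of 22. The highest other split gave 23, so chance cannot be excluded there either. That other split exchanged P0 replicate 4 and P28 replicate 3, so it still held most of the difference between the stages.

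Markers of fibroblasts, leukocytes, epicardium and adipocytes were higher at P28. A lower share of cardiomyocyte RNA as the only cause would raise the markers of all other cell types alike. The leukocyte median instead exceeded the endothelial median by 4.75 (95% bootstrap interval over members 3.48 to 6.02). Both medians were known when they were chosen, and the members share the same libraries, so the interval is not independent support. Depth is argued against, since thinning to equal depth moved the 4 medians by at most 0.196. RNA of other cells stays open as a candidate explanation: of 41 further transcripts of these cell types, 38 were higher at P28 (92.7%), among them Gsn (8035 ± 1206 to 403170 ± 33675), C3 (2576 ± 284 to 24233 ± 2732), Mgp (4519 ± 1726 to 20478 ± 1518) and Fabp4 (2150 ± 386 to 19123 ± 2730). They were listed before their values were read, except that Lpl had been read with the fatty acid genes; without Lpl, Cox8b and Pparg, which stand in other lists, 35 of 38 were higher. The labels name no sort or gate, and expression of these genes by cardiomyocytes of the later stage was not tested.

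Cell cycle genes were lower at P28. Dilution by RNA of other cells would lower sarcomere genes alike, but the mitosis median lay 2.82 below the adult sarcomere median (difference −2.82, interval −3.70 to −2.25). These medians too were known when they were chosen. The sarcomere list was also not a fixed reference, since 9 of its 21 members rose and 3 fell. Thinning to equal depth left the mitosis median at −2.71, against −2.66 with all reads. RNA of erythroid precursors at P0 cannot be told apart from cycling cardiomyocytes, since 4 P0 libraries allow no two-sided exact p below 0.0833 for a relation between the lists; the list means ran in the same order in the 4 libraries (10.43, 10.91, 9.73 and 9.66 for mitosis, 13.47, 13.51, 13.40 and 13.38 for erythroid markers, log2, the latter over a narrow range), and endothelial and endocardial markers were also higher in P0 replicates 1 and 2 (12.74 and 13.03) than in 3 and 4 (12.38 in both). Immediate early and heat shock genes also ran in the order of the mitosis list at P0 (12.98, 13.25, 12.72 and 12.61, log2). The stage of the mice stays open as a biological cause and was not tested.

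Counts of 6 neighbouring mitochondrial genes (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l, positions 7013 to 10173 of the mitochondrial genome) were far below the other mitochondrial mRNAs, for example 254 ± 16.3 for mt-Co3 against 99891 ± 11118 for mt-Cytb at P0. Short gene length was examined through mt-Nd6 alone. With 519 bases it is shorter than mt-Co3 with 784, and it had 21.7 times the value of mt-Co3. However, mt-Nd6 lies on the strand opposite to the 6 genes, and the strand setting is not given. Its count may hold reads of the other strand, so this comparison cannot decide on length. Reads shared with nuclear copies may be the cause: on average 82.7% of the 50-base words of the 6 genes occur in annotated nuclear pseudogenes, against 18.5% for the other 7 mRNAs, though mt-Nd4 (62.2%) and mt-Co1 (51.1%) share many words and kept high counts (20372 ± 2371 and 97416 ± 29103 at P0). The nuclear copies lie on chromosome 1 between 24611535 and 24616197, and a counter that skips reads with several matches would lose such reads, though how multiply matching reads were handled is not given in the sources used here. For mt-Atp8 this stays open, since 0% of its words were found but the annotated pseudogenes skip its stretch.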

How the results depend on the processing

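Cardiomyocyte scaling, thinning to equal depth and the comparison without the P28 libraries 3 and 4 were chosen only after the data were seen. Cardiomyocyte scaling moved the median of all genes from −0.01 to −0.52 and gave 2604 genes higher, 8218 lower and 3993 at least 2-fold lower. By its construction it lowers all genes at P28, because the adult sarcomere mean was higher there. Under it 7223 of the 9412 genes called with the deposited scaling kept their call and sign and 763 changed sign. Among the genes named in the report, the direction of the called gene Hopx reversed, to a log2 fold change of −0.14, not called. Equal nuclear totals gave 3898 genes higher and 6053 lower (median −0.20), quantile normalization 4266 and 5419 (median −0.13), and TMM 4574 and 4946. Of the 9412 genes, 8517 kept their call and sign with equal nuclear totals, 8826 with quantile normalization (7 changed sign), 9210 with edgeR and 9304 with DESeq2 on the recovered reads, which called 4731 and 4666, and 4943 and 4653, genes higher and lower. Apart from the 3 counts under cardiomyocyte scaling, the gene counts of every setting stayed within 1.5 times those reported. Leaving out 1 library gave 4339 to 4729 genes higher, 4027 to 4463 lower, 2626 to 2716 at least 2-fold higher, 1697 to 1876 at least 2-fold lower, 19 to 22 lists, 10 to 11 pairs and a difference in mitochondrial share of 1.41 to 1.73 percentage points. Without the P28 libraries 3 and 4, 4397 genes were higher and 4177 lower, with 19 lists called. With an estimated correlation camera called 1 list (1 up, 0 down), since the correlation within lists is then set by these 8 libraries, while fry, which does not compare a list with other genes, called 26. Without a filter 5036 genes were higher and 5262 lower, and thinned to equal depth, with the filter kept, 4659 and 4484. Whether depth accounts for the change without a filter was not tested.

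Replicate numbers 1 to 4 are shared by both groups, and no label says whether they pair the samples. Deviations of same-numbered libraries correlated between −0.006 and 0.049. P0 libraries 2 and 4 correlated best with their own number, and P0 libraries 1 and 3 with P28 libraries 3 and 1. Correlations this low show no pairing but cannot exclude it. With the replicate block, limma called 4574 genes higher and 4360 lower and 21 lists, the collagens being lost (adjusted p = 0.054). With the replicate block 0 isoform pairs passed, because a sign-flip test of 4 differences cannot reach a p of 0.05; the smallest adjusted p was 0.182.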

Other observations

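Gsn, which encodes the actin-severing protein gelsolin, was read only as a member of the further fibroblast transcripts. It went from 8035 ± 1206 normalized counts at P0 to 403170 ± 33675 at P28 (mean ± SD, n = 4 each; log2 fold change 5.66). Not all genes of that list rose: Fstl1 was at 20072 ± 2172 and 19830 ± 534, and Lamb1 was lower at P28, from 14645 ± 1794 to 5572 ± 232. These genes were singled out after their values were seen.

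The libraries of 1 stage differed in genes of the sex chromosomes. Xist, expressed from the inactive X chromosome of females, and the Y-linked Ddx3y were both read in the 4 P0 libraries (526 to 1101 and 1079 to 2365 normalized counts) and in P28 replicate 1 (480 and 1719). P28 replicate 2 had 0 for Xist and 2598 for Ddx3y, and P28 replicates 3 and 4 had 1047 and 1014 for Xist and 0 for Ddx3y. Libraries with reads of both genes thus appear to hold RNA of both sexes, though no label says whether they are pools. P28 libraries 3 and 4 were also the shallowest, so leaving both out changes sex and depth together. The same P28 libraries 3 and 4 lay on 1 side of the second principal component (−30.3 and −36.1) and libraries 1 and 2 on the other (8.004 and 60.66).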
